A study of Mus musculus with 12 samples.

How the data were processed

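RNA was extracted from kidneys of wild-type C57BL/6 mice that had received cisplatin, a chemotherapy drug that injures the kidney tubule, and was sequenced on bulk tissue. The labels name 3 groups of 4 samples: cisplatin alone (AKI), cisplatin with mesenchymal stem cells from umbilical cord (UC), and cisplatin with pulsed focused ultrasound and the same kind of cells (pFUS_UC). The labels name no uninjured group and no group with ultrasound alone, so neither recovery towards uninjured kidney nor synergy could be tested. Cell dose, ultrasound setting, time of sampling, sex, library selection and strandedness are not given in the sources used here. Samples were taken as separate animals, which the labels do not state.

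The deposited count table holds raw counts per gene for 56748 genes, and a second deposited table holds FPKM values for the same genes and samples. According to the labels the authors used HTSeq, DESeq2 and the mouse build GRCm39 (mm39), with no versions; the aligner is not named. The FPKM values equal counts divided by the listed gene length and by 1 library total per sample, and that total differs from the sample's summed counts, so the authors had scaled it. Gene symbols, identifiers, coordinates, lengths and biotypes were taken from the deposited count table. The annotation at hand for GC content was built on GRCm38; its genes were matched by identifier alone, 98.1% of the tested genes had a GC value, and no coordinate was taken from it. Library totals ran from 17.3 to 25.2 M (mega) counts. A share of 3 counts, the level that a count of 0 cannot exclude, corresponded to 0.119 to 0.173 CPM (counts scaled to a library total of 1 M); such limits cover counting error only.

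Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on all 12 samples together. Genes were kept by edgeR's filterByExpr with the groups (minimum count 10, minimum total 15), which left 16947 genes; libraries were scaled by TMM, and a quasi-likelihood F-test with 9 residual degrees of freedom was applied to each of the 3 comparisons. P values were adjusted by the Benjamini-Hochberg method over the tested genes, with a threshold of 0.05. Log2 fold changes and adjusted p values of single genes are edgeR's unless another tool is named. Their standard errors (SE) were derived as the absolute log2 fold change divided by the square root of edgeR's F statistic. Means are CPM scaled by TMM with their standard deviation (SD). Principal components were computed on log2 CPM (prior count 2) of the 500 most variable genes. Shares of counts and other per-library measures were compared by 2-sided exact permutation tests, adjusted over 24 tests; with 4 against 4 samples the smallest p such a test can give is 0.0286.

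A set of 41 gene lists covering pathways, organelles, kidney cell types, blood cells and neighbouring tissues was tested in each comparison with camera (limma 3.58.1) on voom log2 CPM, which compares a list with all other genes, with a preset inter-gene correlation of 0.01. The same test with a correlation estimated from the data, and fry, which asks whether a list's members move on balance in 1 direction, were run beside it. Adjusted p values of lists are camera's, over the 41 lists of a comparison. The number of members called was counted after adjustment over all tested genes and adjusted over the list alone. Groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined, except for the limits on named genes and the 2 alternatives described below as set or chosen later. Tests of explanations for a pattern were written after the pattern was seen and before their own result, and the test of a library batch after its result.

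Named genes are, per comparison, up to 8 genes per direction with the largest log2 fold change among genes past the threshold, with a mean of at least 5 CPM in the higher group and no overlap between groups; where none pass, 5 genes per direction with the smallest p. Also named are the 3 members with the smallest p in up to 6 lists with the smallest camera p and in lists on the themes of the study's title, up to 2 examples of another list, and Havcr1, Lcn2, Cdkn1a, Hspa1a, Hspa1b and Ppargc1a. Examples were limited to lists that camera called in that comparison, and this limit was set after the data were seen. It left out 124 pairs of gene and comparison, of which 83 had passed edgeR's threshold. Some genes that the rule names are not reported here and were neither replaced nor counted; this was set after the data were seen. With the pairs left out, 43 of 541 groups of 4 values had a library standing apart, against 23 of 340 without those pairs, and 4 of the pairs left out changed sign under an alternative: Hbb-bs and Hbb-bt in pFUS_UC against AKI, and Mmp9 and S100a9 in pFUS_UC against UC.

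Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter, a filter at 1 CPM in 4 samples, fits of only the groups compared, a replicate block, counts thinned to the smallest library, libraries without mitochondrially encoded and the 10 most abundant other genes, limma on log2(FPKM + 1), a 2-fold minimum, and each library left out in turn. Offsets that remove each library's trend over gene length and GC content, and fits without UC replicates 1 and 2, were chosen after seeing the data. The edgeR, DESeq2 and limma fits were tested on simulated data with known changes. The labels do not say whether replicate numbers link samples across groups. Deviations from the group mean correlated between samples of the same number with r of -0.17 to 0.15 over the tested genes, and the number was the best match in 2 of 12 pairs; the fit therefore has no block. The relation between the 2 comparisons with AKI was set beside 20 simulations of unchanged groups against the same controls, and recomputed with the AKI kidneys divided 2 and 2. Figures were drawn with matplotlib 3.10.9.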

Results

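Bulk RNA sequencing counts were compared between kidneys of cisplatin-treated mice that received no cells (AKI), umbilical cord mesenchymal stem cells (UC) or pulsed focused ultrasound and these cells (pFUS_UC), with 4 samples per group. Library totals were 19.3 ± 2.89 M (mega) counts in AKI, 19.5 ± 1.34 M in UC and 21.5 ± 2.74 M in pFUS_UC (SD, n = 4 each). Across the 16947 tested genes, correlations between replicates were 0.967 to 0.981 in AKI, 0.961 to 0.971 in UC and 0.971 to 0.981 in pFUS_UC. Those between AKI and UC samples were 0.900 to 0.960, between AKI and pFUS_UC samples 0.919 to 0.969, and between the MSC groups 0.954 to 0.980; these are across genes, which are not independent replicates. Principal component 1 carried 45.3% of the variance and separated AKI (-37.2 to -16.9) from UC (7.46 to 27.9) and pFUS_UC (3.21 to 18.2). Component 2, with 11.5%, placed pFUS_UC replicate 4 at 30.3, and the other pFUS_UC samples at 1.45 to 5.42.

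The AKI libraries differed from those of both MSC groups in composition. Mitochondrially encoded genes held 5.0 ± 1.88% of counts in AKI, 14.2 ± 5.17% in UC and 12.3 ± 3.67% in pFUS_UC (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.049, for each MSC group against AKI). Ribosomal protein genes held 1.82 ± 0.123%, 3.23 ± 0.280% and 2.92 ± 0.214%, and long noncoding RNAs 0.580 ± 0.143%, 1.06 ± 0.0660% and 0.997 ± 0.130%, with the same exact permutation p against AKI. The rank correlation of a library's expression, relative to the mean of all libraries, with gene length over protein-coding genes was 0.233 ± 0.101 in AKI, -0.174 ± 0.0328 in UC and -0.153 ± 0.113 in pFUS_UC, again with an exact permutation p of 0.0286 for each MSC group against AKI. The 4 AKI samples also carry another kind of sample code than the 8 MSC samples, so a batch of library preparation and the AKI group cannot be told apart. Rn18s-rs5, a sequence related to the 18S ribosomal RNA gene, held 0.495 ± 0.125% in AKI, 0.638 ± 0.116% in UC and 1.02 ± 0.166% in pFUS_UC. In this share pFUS_UC lay above AKI and above UC (exact permutation p = 0.0286, adjusted p = 0.049, for each), and UC against AKI had p = 0.2 (adjusted p = 0.282). The adjustment pools 24 tests of all 3 comparisons, and most of its smallest p values are against AKI. The share of this gene alone does not give the ribosomal RNA content of a library.

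**Figure D1:**
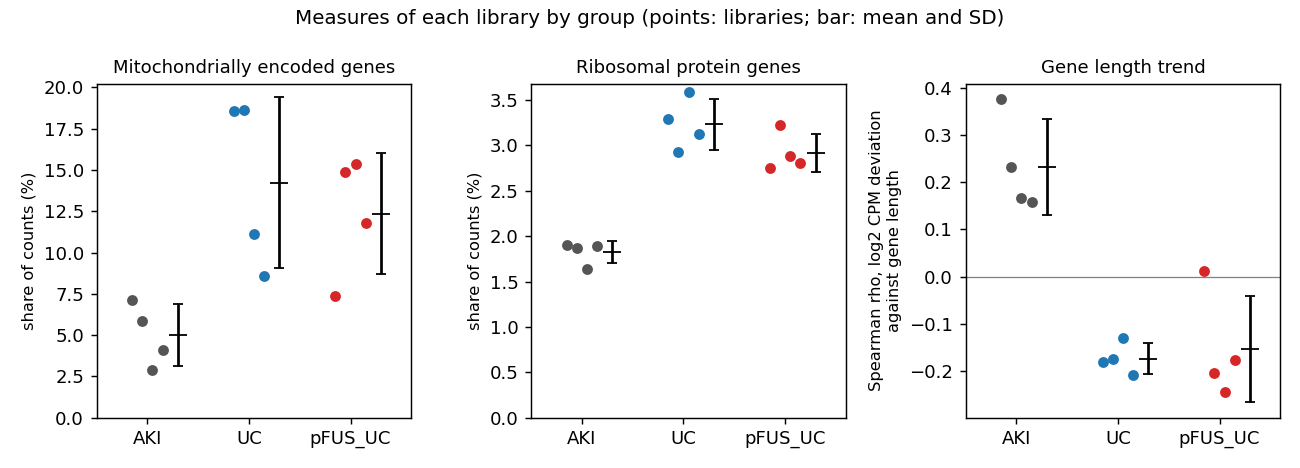
The share of counts from mitochondrially encoded genes (%), the share from ribosomal protein genes (%) and the rank correlation with gene length are plotted for each of the 12 libraries, with the mean and SD of each group of 4. The AKI mitochondrial shares lie between 2.87 and 7.12%, and those of UC between 8.57 and 18.6%.

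The comparison of UC with AKI asks what the cells alone did in the injured kidney. Genes for the respiratory chain and for ribosomal proteins were higher in UC kidneys, while genes of podocytes (the filter cells of the glomerulus), endothelium and extracellular matrix were lower. Of 13 mitochondrially encoded respiratory chain genes 12 rose (median log2 fold change 2.16), as did 30 of 37 nuclear genes of complex I (median 0.82, 1 fell) and 28 of 40 of complexes II to V (median 0.67, 3 fell). Of 51 cytosolic ribosomal protein genes 47 rose (median 1.08). All 12 podocyte genes fell (median -2.30), as did 29 of 32 matrix and fibroblast genes (median -1.76) and 15 of 20 endothelial genes (median -1.59, 1 rose). In total 8210 of 16947 genes passed edgeR's threshold, 4085 higher and 4125 lower, and 3349 of them changed at least 2-fold. The groups did not overlap for 41.7% of genes, where chance gives 2.86%.

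The mitochondrially encoded genes that rose included mt-Co3, a subunit of cytochrome c oxidase (ENSMUSG00000064358, mitochondrial genome 8607 to 9390, GRCm39), with 1156 ± 494 CPM in UC and 120 ± 59.6 CPM in AKI (log2 fold change 3.26, SE 0.46, adjusted p = 0.000138). mt-Co2 rose by 3.17, mt-Atp6 by 3.08 and mt-Nd3 by 3.59. These genes were picked by size of rise and lay above the list median of 2.16. The more abundant mt-Co1 was at 12904.9 to 29340 CPM in AKI libraries and 31749.2 to 83733.5 CPM in UC libraries. The mitochondrially encoded share of counts rose 2.849-fold, against 9.6-fold for mt-Co3. Nuclear pseudogene copies of mitochondrial sequence rose as well, Gm28661 by 2.82, Gm29216 by 3.25 and Gm28437 by 2.71 (chosen after their values were seen). They share sequence with the genes, and whether shared reads bear on the size of these rises was not tested. Among nuclear respiratory genes Ndufb2 rose by 1.76 (25.9 ± 3.98 against 7.66 ± 1.11 CPM), Ndufc1 by 1.39, Ndufs6 by 1.29, Cox6c by 1.80, Atp5k by 1.41 and Uqcrh by 1.08. Rps27a rose by 2.23, Rps24 by 1.54 and Rpl23 by 1.5. Camera's adjusted p values were 1.85e-05 for the mitochondrially encoded list, 7.39e-11 for complex I, 3.38e-08 for complexes II to V and 1.69e-20 for ribosomal proteins; with an estimated correlation the adjusted p values were 0.75, 0.681, 0.681 and 0.475. With length and GC offsets, chosen after seeing the data, the mitochondrially encoded median was 0.65 (adjusted p = 0.018); without UC replicates 1 and 2, the libraries with the highest mitochondrial shares (18.6% each), it was 1.41. These offsets put mt-Nd3 at 1.65, mt-Co2 at 1.96, mt-Atp6 at 1.77, Atp5k at 0.92 and Uqcrh at 0.71.

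Podocyte genes that fell included Synpo, an actin-binding protein of foot processes (ENSMUSG00000043079, chromosome 18, 60727045 to 60793214), at 31.4 ± 4.79 CPM in UC and 177 ± 41.0 CPM in AKI (log2 fold change -2.49, SE 0.21, adjusted p = 2.3e-05). Nphs1, which encodes nephrin of the slit diaphragm, fell by 2.42 and Clic5 by 1.37. Of endothelial genes the VEGF receptors Kdr and Flt1 fell by 3.40 and 2.46, and the transcription factor Sox18 by 2.55. Of matrix genes Dcn fell by 2.55, Col4a2 by 1.75 and Col4a1 by 1.72. Camera's adjusted p was 1.31e-08 for podocytes, 7.67e-06 for endothelial cells and 5.82e-11 for matrix, and 0.475, 0.75 and 0.553 with an estimated correlation.

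Further lists that camera called lower in UC than in AKI had smaller shares of changed members. They were mechanosensitive channels and YAP targets (12 of 20 fell, adjusted p = 0.00142; Crim1 -1.55, Axl -1.74), proximal tubule (14 of 38 fell and 2 rose, 0.0122; Slc3a1 -1.96, Hnf4a -0.91), endoplasmic reticulum chaperones (11 of 29 fell and 3 rose, 0.0156; Edem1 -1.02, Sel1l -0.88) and the tricarboxylic acid cycle (7 of 20 fell, 0.0156; Pdha1 -1.0). Immediate early genes (12 of 29 fell, 0.0245; Klf4 -1.83, Klf2 -1.5), autophagy (11 of 25 fell and 2 rose, 0.0275; Atg9a -2.19, Nbr1 -0.69) and macrophages (4 of 20 fell, 0.0407; Mrc1 -1.82, Mpeg1 -1.27) followed. Of all 16947 tested genes 4125 fell in UC, and the macrophage share of 4 of 20 was not above that. With an estimated correlation the adjusted p values of these lists were 0.424, 0.826, 0.826, 0.827, 0.827, 0.595 and 0.826 in the order given. The tricarboxylic acid call was lost without UC replicate 3 (median -0.11, adjusted p = 0.0649), while its median was -0.31 without UC replicates 1 and 2 (camera adjusted p = 0.00227). The autophagy call was lost without AKI replicate 4 (0.0511, median -0.18) and with length and GC offsets (0.243, median -0.21 in place of -0.22). The immediate early call was lost without AKI replicate 4 (0.0666), UC replicate 2 (0.0525) or UC replicate 4 (0.0971). Fry ended the immediate early (0.105) and macrophage (0.0568) calls. That of macrophages was lost without AKI replicate 3 (0.0896) or 4 (0.0657), without UC replicate 1 (0.0663), 2 (0.0774) or 3 (0.0639), and without UC replicates 1 and 2 together (0.221), where its median was -0.33 and Mpeg1 was at -0.84 (0.0623). By limma on log2(FPKM + 1) Mrc1 was at -0.48 and Mpeg1 at -0.71, both still called. With length and GC offsets the YAP median of -0.63 was -0.28, Sel1l was at -0.51 and Nbr1 at -0.40.

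Single genes with the largest rises in UC against AKI were led by Gapdh, a glycolytic enzyme with many pseudogenes (ENSMUSG00000057666, chromosome 6, 125138678 to 125143430), at 198 ± 181 against 8.15 ± 1.74 CPM (log2 fold change 4.60, SE 1.24, adjusted p = 0.00808). Whether reads shared between Gapdh and its pseudogenes set these values was not tested, so its rise is not read as a change in expression. AI838599, Snhg14 and Doc2g rose by 3.18, 3.05 and 2.94. Igfbp3, an insulin-like growth factor binding protein (ENSMUSG00000020427, chromosome 11, 7156086 to 7163923), was at 39.6 ± 9.80 against 447 ± 157 CPM (log2 fold change -3.50, SE 0.25, adjusted p = 1.06e-05). A2m, Igha, Mfsd9, Ston1, Plin1 and Cyyr1 fell by 3.98, 3.87, 3.72, 3.45, 3.44 and 3.33. By limma on log2(FPKM + 1) these 6 were at -1.55, -1.60, -1.19, -2.10, -1.15 and -1.02, Snhg14 at 0.54 (2.03 with 0.1 in place of 1) and Doc2g at 1.39, all still called. Heat shock genes moved both ways: 4 of 35 rose and 4 fell (median 0.08, adjusted p = 0.92), Ptges3 (1.07) and Cacybp (0.84) among the first and Serpinh1 (-1.11) among the second; with length and GC offsets Ptges3 was at 0.66 and Cacybp at 0.41. Of 26 genes of mitochondrial biogenesis, dynamics and mitophagy 3 rose and 8 fell (adjusted p = 0.446), with Fis1 at 0.92, Esrrg at -0.95 and Mfn2 at -1.08. Among all tested genes 48.4% were called, a larger share than in the heat shock or the biogenesis list. Havcr1, the tubular injury marker KIM-1, was at 126 ± 72.0 and 72.9 ± 35.6 CPM (adjusted p = 0.397), Lcn2 had a log2 fold change of 1.30 (adjusted p = 0.137; 1.94 and 0.0474 without AKI replicate 2), Cdkn1a of -0.20 (0.803), Hspa1a of 0.31 (0.755), Hspa1b of -0.07 (0.909) and Ppargc1a of -0.19 (0.452). Without UC replicate 3, at 65.6 CPM, Hspa1a was at -1.67 (adjusted p = 0.00883).

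Adjusted over the list alone, the numbers that rose or fell in UC against AKI were 13 for the mitochondrially encoded genes, 31 and 1 for complex I, 29 and 4 for complexes II to V, 48 for ribosomal proteins, 12 for podocytes, 29 for matrix, and 16 with 1 rise for endothelial cells. Length and GC offsets left 7591 called genes, 6124 of them shared with the 8210, and 54.5% of them higher. Without UC replicates 1 and 2, 5416 genes were called and 5198 were shared.

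**Figure D2:**
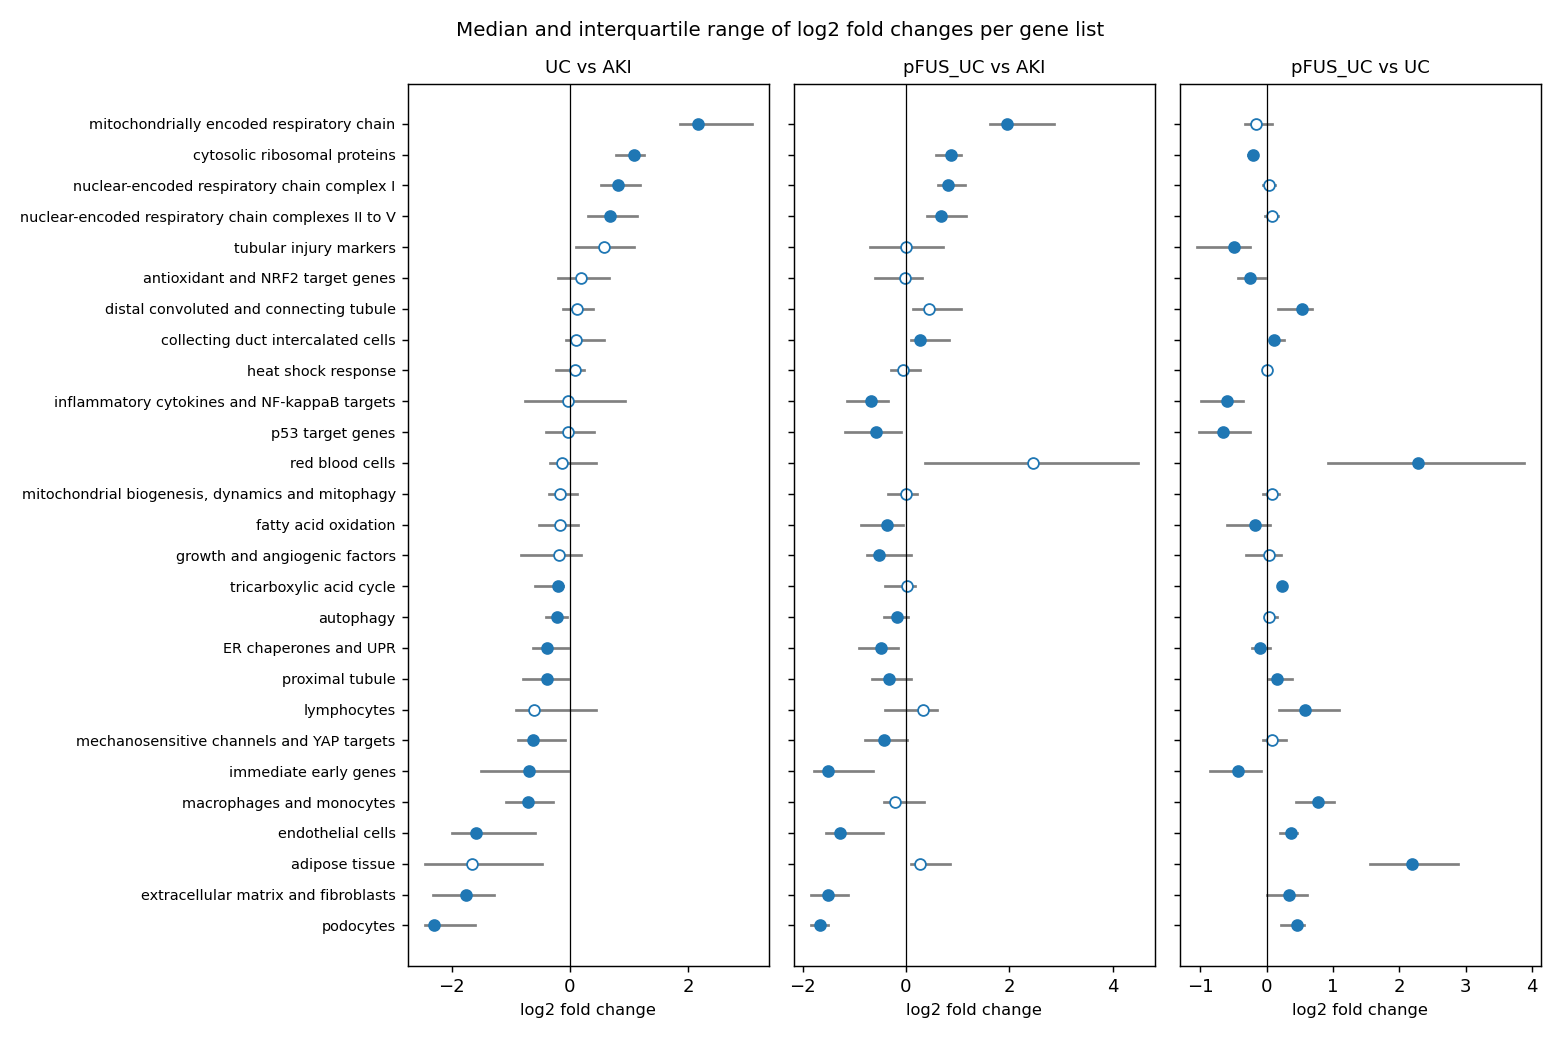
The median log2 fold change of each of 27 gene lists is plotted for the 3 comparisons, with lines for the interquartile range of the members and filled points where camera's adjusted p was under 0.05. Respiratory chain and ribosomal protein medians lie above 0 and podocyte, endothelial and matrix medians below 0 in both comparisons with AKI. In pFUS_UC against UC the medians of adipose tissue (2.19) and red blood cells (2.28) lie above 2.

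The comparison of pFUS_UC with AKI asks what ultrasound and cells together did. As in UC, respiratory chain and ribosomal protein genes were higher and podocyte, endothelial and matrix genes lower; immediate early genes, which respond first to stress and growth signals, were lower too. Of the 13 mitochondrially encoded genes 11 rose (median 1.95), of 37 complex I genes 30 (median 0.81), of 40 genes of complexes II to V 30 (median 0.69) and of 51 ribosomal protein genes 44 (median 0.88). All 12 podocyte genes fell (median -1.66), as did 26 of 32 matrix genes (median -1.5), 12 of 20 endothelial genes (median -1.28, 2 rose) and 18 of 29 immediate early genes (median -1.5). In total 7463 genes passed edgeR's threshold, 3715 higher and 3748 lower, 2840 of them at least 2-fold, and 40.8% of genes did not overlap between the groups. Adjusted over the list alone, 13 mitochondrially encoded, 31 complex I, 31 complexes II to V (1 fell), 46 ribosomal protein, 12 podocyte, 27 matrix, 15 endothelial (2 rose) and 19 immediate early genes passed in these directions.

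Camera's adjusted p values in pFUS_UC against AKI were 2.18e-05 for the mitochondrially encoded list, 1.13e-12 for complex I, 2.75e-10 for complexes II to V, 1.59e-16 for ribosomal proteins, 2.41e-08 for podocytes, 2.19e-09 for matrix, 8.23e-05 for endothelial cells and 2.18e-05 for immediate early genes. With an estimated correlation these adjusted p values were 0.661, 0.528, 0.528, 0.528, 0.528, 0.528, 0.734 and 0.686. With length and GC offsets the mitochondrially encoded median was 0.74 (adjusted p = 0.0368) and that of complex I 0.53. mt-Nd3 rose by 3.94, mt-Co2 by 3.25, mt-Atp6 by 3.05 and mt-Co3 by 2.86, and the pseudogene copies Gm28661, Gm29216 and Gm28437 by 2.85, 3.20 and 2.69. mt-Co1 was at 25625.1 to 60322.8 CPM in pFUS_UC libraries, which overlaps the AKI libraries (12904.9 to 29340 CPM). The mitochondrially encoded share of counts rose 2.472-fold, against 7.26-fold for mt-Co3. Atp5k rose by 1.78, Cox6c by 1.77, Ndufb2 by 1.68, Cox7c by 1.44, Ndufc1 by 1.39 and Ndufs6 by 1.30, and Rps29, Rps24 and Rpl37 by 1.63, 1.34 and 1.24. Kdr fell by 2.57, Synpo by 2.18, Flt1 by 1.99, Col4a2 by 1.84, Col4a1 and Dcn by 1.77, Klf4 by 1.69, Klf2 by 1.44 and Clic5 by 1.15. With these offsets mt-Nd3 was at 2.09, mt-Co2 at 2.06, mt-Atp6 and mt-Co3 at 1.78, Ndufc1 at 0.91 and Cox7c at 0.82.

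More lists lay lower in pFUS_UC than in AKI. Fatty acid oxidation (11 of 30 fell, 1 rose, adjusted p = 0.0134; Ppara -2.03, Acadvl -1.51), endoplasmic reticulum chaperones (14 of 29 fell, 1 rose, 0.000381; Edem1 and Sel1l -0.98) and mechanosensitive channels and YAP targets (11 of 20 fell, 0.00321; Crim1 -1.28, Pkd1 -0.73) were among them. So were inflammatory cytokines and NF-kappaB targets (8 of 23 fell, 1 rose, 0.0247; Icam1 -1.68, Csf1 -1.39), p53 targets (10 of 30 fell, 1 rose, 0.0423; Zmat3 -1.40, Sesn2 -0.84) and growth factors (10 of 26 fell, 3 rose, 0.0423; Bmp6 -1.32, Igf1r -0.64). Proximal tubule (11 of 38 fell, 1 rose, 0.0423; Slc3a1 -1.68, Slc7a7 -1.16) and autophagy (10 of 25 fell, 1 rose, 0.0464; Atg9a -1.88, Ulk1 -0.65) completed them, while intercalated cells lay higher (6 of 14 rose, 0.0423; Atp6v1g3 1.25, Atp6v1c2 0.64). Of all 16947 tested genes 3748 fell and 3715 rose. With an estimated correlation the adjusted p values of these lists were 0.769, 0.562, 0.498, 0.769, 0.956, 0.498, 0.766, 0.543 and 0.766 in the order given. Fry ended 4 of these calls, p53 targets (0.248), NF-kappaB targets (0.0915), fatty acid oxidation (0.0677) and proximal tubule (0.0609). A left-out library ended 7 of these calls. Fatty acid oxidation was at 0.077 without AKI replicate 2, and growth factors at 0.0734 without AKI replicate 1. NF-kappaB targets were at 0.0563 without AKI replicate 2 and 0.103 without pFUS_UC replicate 4. The p53 call ended without AKI replicate 1 (0.114), 2 (0.118) or 4 (0.0743) and without pFUS_UC replicate 4 (0.174, median -0.38 in place of -0.58). Proximal tubule was lost without AKI replicate 3 (0.0919) or 4 (0.0743) or pFUS_UC replicate 1 (0.077) or 2 (0.0687). Autophagy was lost without AKI replicate 2 (0.077) or 4 (0.0747) or pFUS_UC replicate 2 (0.0519) or 3 (0.0515), with a median of -0.26 in place of -0.17 without AKI replicate 1, and intercalated cells without AKI replicate 1 (0.0503) or 2 (0.077) or pFUS_UC replicate 2 (0.121); the intercalated median of 0.26 was 0.43 without AKI replicate 3. Length and GC offsets ended YAP targets (0.09, median -0.10), growth factors (0.09, median -0.31), autophagy (0.459, median -0.13) and intercalated cells (0.0751, median 0.46 in place of 0.26), and with them Igf1r (-0.23, adjusted p = 0.0811) and Ulk1 (-0.24, 0.105) lost their calls, while Pkd1 (-0.23), Atp6v1g3 (0.46) and Sel1l (-0.64) moved towards 0 and stayed called.

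Cdkn1a, the p53-induced cell cycle inhibitor p21 (ENSMUSG00000023067, chromosome 17, 29309950 to 29319701), fell from 144 ± 82.9 CPM in AKI to 41.1 ± 28.0 CPM in pFUS_UC (log2 fold change -1.80, SE 0.63, adjusted p = 0.0317); the call was lost at -1.51 (adjusted p = 0.0868) without AKI replicate 2, -1.63 (0.0745) without AKI replicate 4, -1.78 (0.0707) without pFUS_UC replicate 2, -1.86 (0.0635) without pFUS_UC replicate 3 and -1.67 (0.051) with length and GC offsets. Gapdh rose by 4.28 (158 ± 279 CPM, adjusted p = 0.0125), a rise carried by pFUS_UC replicate 3, without which it was 1.22 (0.178); it was 2.44 (0.105) with a replicate block and 2.05 (0.129) by limma on log2(FPKM + 1). Reads shared with Gapdh pseudogenes were not examined here either. Havcr1 had a log2 fold change of -1.19 (adjusted p = 0.214), Lcn2 of -0.28 (0.764), Hspa1a of -0.67 (0.504), Hspa1b of -0.12 (0.856) and Ppargc1a of 0.20 (0.457). Of 35 heat shock genes 4 rose and 5 fell (median -0.06, camera direction up, adjusted p = 0.917), with Ptges3 at 1.04, Cacybp at 0.84 and Hsf2 at 0.82; with length and GC offsets Ptges3 was at 0.61 and Cacybp at 0.40 (adjusted p = 0.0551). Of 26 biogenesis, dynamics and mitophagy genes 5 rose and 7 fell (adjusted p = 0.909), with Fis1 at 0.86, Dnm1l at 0.75 and Mfn2 at -0.94. Among all tested genes 44% were called, a larger share than in the heat shock list and close to that of the biogenesis list. AI838599, Mir99ahg and Snhg14 rose by 2.99, 2.80 and 2.70. Pcdhgc3, Cyp26b1, Egr2, C7, Ston1, Adra1b, Adnp and Ak5 fell by 3.31, 3.26, 3.24, 3.23, 3.13, 3.07, 3.01 and 2.98. By limma on log2(FPKM + 1) Pcdhgc3, Cyp26b1, Egr2, Ston1, Adra1b, Adnp and Ak5 were at -1.23, -1.98, -1.32, -1.98, -1.51, -1.01 and -1.41, Mir99ahg at 0.57, Snhg14 at 0.43 (1.76 with 0.1 in place of 1) and Hsf2 at 0.45, all still called.

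**Figure D3:**
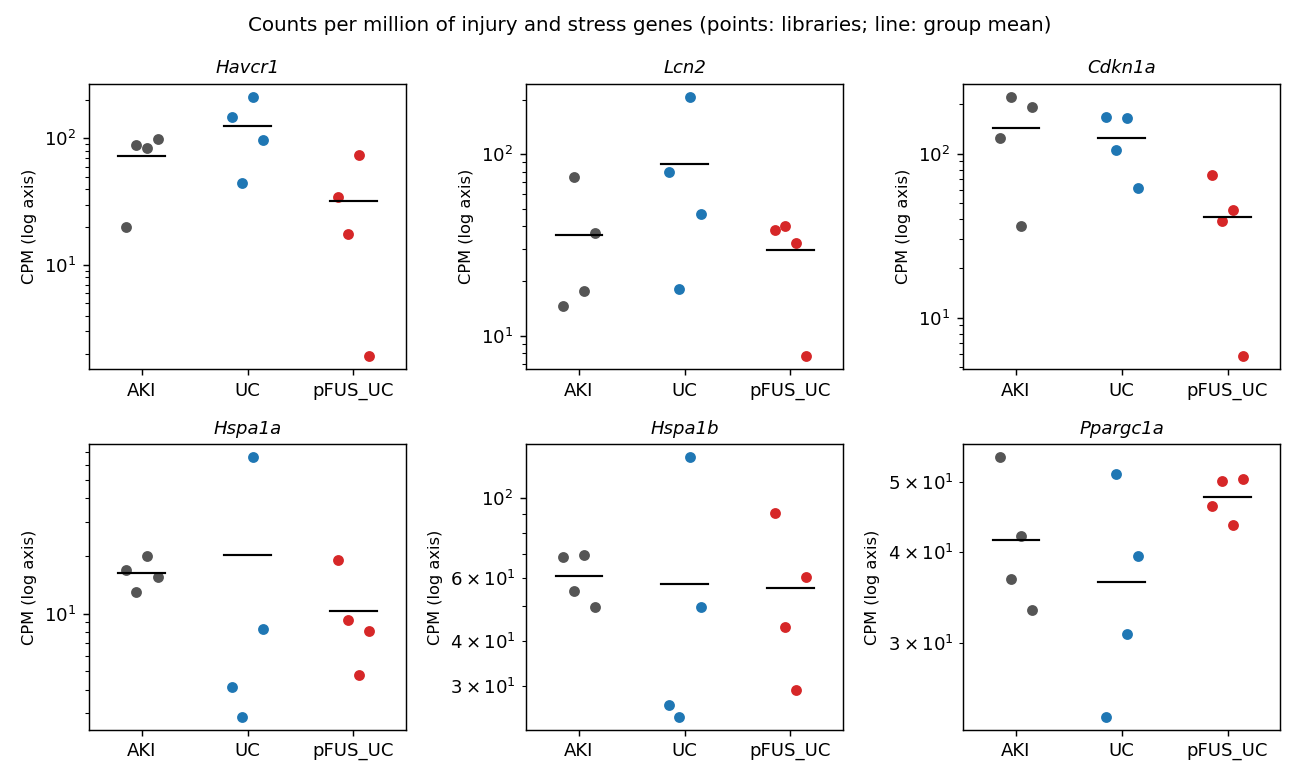
CPM of Havcr1, Lcn2, Cdkn1a, Hspa1a, Hspa1b and Ppargc1a is plotted on log axes for each of the 12 libraries, with a line at each group's mean. Havcr1, Lcn2 and Cdkn1a spread widely within the groups, and pFUS_UC replicate 4 has 1.92 CPM of Havcr1.

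The changes of both MSC groups against AKI resembled each other. Across genes, log2 fold changes correlated with a Pearson coefficient of 0.90 and a Spearman coefficient of 0.90, where simulated unchanged groups sharing the AKI controls gave 0.50 and 0.46 on average. Their covariance was 0.697 against 0.0537 in the simulations. With the AKI kidneys divided 2 and 2 between the comparisons, the Pearson coefficient averaged 0.76 (0.70 to 0.81 over 6 assignments) and the covariance 0.662. Called in both comparisons were 3195 higher and 3247 lower genes, with the AKI kidneys shared. With divided AKI kidneys these averaged 1781 and 2196, where independent calls would share 462 and 557. A batch that coincides with the AKI group would be common to both comparisons as well. Dividing the AKI kidneys does not remove it and the simulations held no batch, so these values do not separate treatment from batch. The differences in the mitochondrial, ribosomal protein and long noncoding RNA shares and in the length trend are common to both comparisons, and that in the Rn18s-rs5 share is not.

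The comparison of pFUS_UC with UC asks what ultrasound added to the cells. No single gene passed edgeR's threshold (0 of 16947), while groups of genes lay together on 1 side. Genes of the p53 response, tubular injury, inflammation and ribosomal proteins lay lower in pFUS_UC, and genes of fat tissue, macrophages, distal tubule and the tricarboxylic acid cycle higher. Medians of these lists against AKI are given in the next paragraph. Negative log2 fold changes were found for 26 of 30 p53 targets (median -0.65, adjusted p = 2.31e-10), 24 of 26 injury markers (-0.48, 8.43e-06), 21 of 23 inflammatory genes and NF-kappaB targets (-0.60, 7.46e-06) and 48 of 51 ribosomal protein genes (-0.20, 1.78e-10). Positive ones were found for 13 of 13 adipose genes (2.19, 2.01e-09), 18 of 20 macrophage genes (0.78, 3.28e-07), 13 of 14 distal and connecting tubule genes (0.54, 4.41e-06) and 20 of 20 tricarboxylic acid cycle genes (0.23, 3.05e-07). With an estimated correlation the adjusted p was 0.449 for each of these 8 lists, and fry called 0 of the 41 lists. The Rn18s-rs5 share, 1.02% in pFUS_UC and 0.638% in UC, was the 1 measure of 8 per library that differed between these groups (exact permutation test, adjusted p = 0.049). Without UC replicates 1 and 2 the medians were 0.46 for macrophages, 1.37 for adipose tissue and -0.13 for ribosomal proteins. Without UC replicate 4 the macrophage median was 1.24; without pFUS_UC replicate 4 the injury median was -0.31 and the inflammatory median -0.35, which was -0.28 without UC replicate 1.

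In the comparisons with AKI neither the injury nor the adipose list was called. Injury markers had a median of 0.57 in UC (7 of 26 rose and 1 fell, adjusted p = 0.189) and 0.00 in pFUS_UC (2 rose and 3 fell, 0.909), which was -0.22 without pFUS_UC replicate 1 and 0.16 without AKI replicate 2. Of all 16947 tested genes 4085 rose in UC, a share close to that of the injury markers. Adipose genes had a median of -1.65 in UC (6 of 13 fell, adjusted p = 0.0507) and 0.27 in pFUS_UC (1 rose, 0.871). The adipose list was, however, called lower in UC without AKI replicate 2 (median -1.82, adjusted p = 0.0181) or 4 (-1.95, 0.0441), UC replicate 3 (-2.70, 0.0306) or pFUS_UC replicate 2 (0.0187), 3 (0.0429) or 4 (0.0495), with a replicate block (-1.90, 0.00258) and with length and GC offsets (-1.68, 0.0332). Its adjusted p was 0.827 with an estimated correlation and 0.101 with fry. Macrophage medians against AKI were -0.71 in UC and -0.22 in pFUS_UC. Those of the tricarboxylic acid cycle were -0.20 and 0.03, and those of ribosomal proteins 1.08 and 0.88. For these lists, and for podocytes, endothelium and matrix, pFUS_UC lay nearer AKI than UC did. For p53 targets (-0.03 and -0.58), inflammatory genes (-0.03 and -0.67) and distal tubule (0.11 and 0.45) pFUS_UC lay further from AKI.

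Members of these lists had wide spreads between replicates in pFUS_UC and UC. Cdkn1a was at 41.1 ± 28.0 CPM in pFUS_UC and 125 ± 51.3 CPM in UC (log2 fold change -1.60, adjusted p = 0.598), Havcr1 at 31.9 ± 30.8 and 126 ± 72.0 CPM (-1.97, 0.597) and Lcn2 at 29.7 ± 15.0 and 88.1 ± 83.6 CPM (-1.57, 0.619). Over the alternatives Cdkn1a ran from -2.05 to -1.24, Havcr1 from -2.80 to -1.58 and Lcn2 from -2.11 to -0.70. Log2 fold changes were -1.63 for Plk3, -1.24 for Ckap2, -0.65 for Bax, an effector of apoptosis, -1.59 for Tnfrsf12a, -1.08 for Spp1, -2.85 for the neutrophil chemokine Cxcl1 and -1.03 for Il34, each with an adjusted p of 0.591. Cxcl1 ran from -3.44 to -1.46 over the alternatives. Rpl30 and Rps7 were at -1.03 and -0.32. The adipocyte genes Adipoq, Plin1 and Fabp4 were at 2.89, 2.76 and 1.63, the macrophage genes Mrc1, Aif1 and Mpeg1 at 1.35, 1.06 and 1.03, the distal tubule genes Pvalb, Slc12a3 and Klhl3 at 1.38, 0.98 and 0.57, and Idh3b, Idh3a and Dlat at 0.38, 0.29 and 0.27.

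Other lists lower in pFUS_UC than in UC were immediate early genes (median -0.43, adjusted p = 7.84e-06; Dusp5 -1.44, Klf6 -0.98), antioxidant and NRF2 targets (-0.25, 2.82e-05; Srxn1 -0.66, Gclc -0.65), fatty acid oxidation (-0.17, 0.0169; Fabp1 -1.72, Plin2 -1.65) and endoplasmic reticulum chaperones (-0.10, 0.0324; Xbp1 -0.61, Atf4 -0.45). Higher were endothelial cells (0.36, 5.25e-05; Kdr 0.83, Flt1 0.47), matrix (0.34, 5.34e-05; Lum 1.55), podocytes (0.46, 0.000228; Thsd7a 0.52) and lymphocytes (0.58, 0.00681; Ighm 1.08). So were intercalated cells (0.11, 0.0184; Slc4a1 0.89, Atp6v1c2 0.29), red blood cells (2.28, 0.0251; Hbb-bt 4.78) and proximal tubule (0.16, 0.0378; Cyp4b1 0.54, Slc4a4 0.48). With an estimated correlation the adjusted p values were 0.449, 0.449, 0.609, 0.558, 0.449, 0.449, 0.449, 0.449, 0.483, 0.449 and 0.558 in that order. Fatty acid oxidation was lost without UC replicate 1 (0.102, median -0.10) or 2 (0.153, median -0.09) or pFUS_UC replicate 2 (0.103), and its median was -0.26 without UC replicate 3. Endoplasmic reticulum chaperones were lost without UC replicate 3 (0.536, median -0.03) or pFUS_UC replicate 2 (0.187, median -0.06) or 3 (0.156), with a median of -0.17 without UC replicate 2, and lymphocytes without UC replicate 2 (0.0656). Intercalated cells were lost without UC replicate 3 (0.346) or pFUS_UC replicate 2 (0.26; median 0.06 in both), and red blood cells without UC replicate 4 (0.13) or pFUS_UC replicate 4 (0.336), in which Hbb-bt reached 30.9 CPM. Proximal tubule was lost without AKI replicate 1 (0.0505), UC replicate 3 (0.755, median 0.09) or pFUS_UC replicate 3 (0.135) or 4 (0.202). Without UC replicates 1 and 2 the antioxidant (0.149), matrix (0.198) and lymphocyte (0.36) calls were lost, and the medians of fatty acid oxidation (0.02) and endothelial cells (-0.02) changed sign. In that fit the median was 0.31 for intercalated cells and 3.94 for red blood cells. Medians also moved for immediate early genes (-0.25 without UC replicate 1, -0.76 and -0.24 without pFUS_UC replicates 1 and 4), matrix (0.62 without UC replicate 4), podocytes (0.29 without UC replicate 3), endothelial cells (0.16, 0.23 and 0.62 without UC replicates 1, 2 and 4), lymphocytes (1.33 without UC replicate 4), intercalated cells (0.28 without UC replicate 1, 0.21 without pFUS_UC replicate 1) and red blood cells (3.53 without UC replicate 1, -0.15 without pFUS_UC replicate 4).

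Heat shock and mitochondria are the themes of the study's title; between pFUS_UC and UC the heat shock list was not called, and the calls of mitochondrial lists depended on the list and on single libraries. Of 35 heat shock genes 0 passed edgeR's threshold (0 adjusted over the list alone; median 0.00, adjusted p = 0.961), with Hspb1 at -0.66, Hspa1a at -0.99, Serpinh1 at 0.25 and Hspa1b at -0.04. Without UC replicate 3 (65.6 CPM of Hspa1a, others 2.89 to 8.32) Hspa1a was at 1.0 and Hspa1b at 0.74, both opposite in sign; Hspb1 ran from -1.04 to -0.11 over the alternatives. Medians were 0.04 for complex I (adjusted p = 0.561; Ndufs1 0.28, Ndufc2 0.19, Ndufv2 0.19), 0.08 for complexes II to V (0.0888; Atp5k 0.37, Uqcrc2 0.29, Atp5c1 0.28), -0.16 for the mitochondrially encoded genes (0.474; mt-Co3 -0.40, mt-Nd5 -0.36, mt-Nd1 -0.34) and 0.08 for biogenesis, dynamics and mitophagy (0.0816; Esrrg 0.38, Nrf1 -0.23, Ppargc1a 0.39). Without UC replicates 1 and 2 these 4 medians were 0.19 (adjusted p = 2.09e-05), 0.16 (2.45e-05), 0.51 (0.00302) and 0.08 (0.0305). With 1 library left out, camera called complex I without UC replicate 2 (median 0.15, adjusted p = 0.00778) or pFUS_UC replicate 1 (0.14, 0.000185), and biogenesis without UC replicate 2 (0.13, 0.0204). It called complexes II to V without UC replicate 1 (0.11, 0.0161) or 2 (0.10, 0.00359) or pFUS_UC replicate 1 (0.14, 4.24e-05). The tricarboxylic acid cycle list, given above, was called higher in all 12 fits without 1 library (median 0.16 to 0.28, highest adjusted p = 0.000297), all with the preset correlation. These include the 4 fits without an AKI library, which is in neither group compared here. The list's adjusted p was 0.449 with an estimated correlation and 0.264 with fry.

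edgeR's count of 0 in pFUS_UC against UC stood beside 1342 genes with an unadjusted p under 0.05, where 847 would be expected by chance, 44 genes called by DESeq2 and 0 by limma on log2(FPKM + 1). The 1342 became 729 without UC replicate 1 and 785 without pFUS_UC replicate 4, both under 847, and 2209 without UC replicate 4, so the excess over chance depends on single libraries. The groups did not overlap for 3.9% of genes, where chance gives 2.86%. Where few genes were changed in simulated data, edgeR called 53.7% of 2-fold and 86.4% of 4-fold changes in this comparison. Smaller changes would thus often be missed here if few genes changed. This does not hold where many genes change: in UC against AKI 8210 genes were called, of which 3349 changed at least 2-fold. The smallest p belonged to Prlr, the prolactin receptor (ENSMUSG00000005268, chromosome 15, 10177324 to 10349266), at 127 ± 58.3 CPM in pFUS_UC and 39.2 ± 5.02 CPM in UC (log2 fold change 1.70, SE 0.27, adjusted p = 0.351; 0.0166 without pFUS_UC replicate 4). After it came Ccl21a (2.5), Igkc (1.92), Postn (1.47) and Apoc1 (1.34) among higher genes, and Tmc5 (-1.76), Rrp36 (-0.70), Faap20 (-0.67), A4galt (-0.62) and Rrad (-0.58) among lower ones, each with an adjusted p of 0.433 or 0.472. DESeq2 called all 10 of these genes (adjusted p from 4.5e-06 for Prlr to 0.0462 for Tmc5) and the adipocyte genes Plin1, Fabp4 and Adipoq (0.00158, 0.00594 and 0.00343), and the fit with no filter called Prlr (0.000552), Ccl21a (0.0176), Igkc (0.0315), Postn (0.0438), Plin1, Fabp4 (0.0255 each) and Adipoq (0.0315). Adjusted over the list alone, 8 adipose genes, 2 matrix genes, 2 skeletal muscle genes and 1 gene each of the lymphocyte, antioxidant, biogenesis, circadian and female-biased lists passed, and 0 of p53, injury and inflammatory lists.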

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

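The test of a library batch was chosen only after the result was seen; the length and GC offsets and the fits without UC replicates 1 and 2 were chosen after seeing the data.

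Respiratory chain and ribosomal protein genes were higher in both MSC groups than in AKI kidneys. A trend over listed gene length between the libraries is argued against as the whole cause for the ribosomal protein and nuclear respiratory lists. The lowest of their 6 medians lay at percentile 99.61 of 10000 random lists matched on listed length and expression. Median listed lengths were 2007 bp for ribosomal protein and 1569 bp for complex I genes. A trend over the length of the transcripts present was not tested. Random genes were drawn independently, so the percentile takes no account of correlation within a list. A library batch cannot be told apart from the AKI group, since 0 of the 3 groups held both kinds of sample code. Whether RNA without a poly(A) tail was recovered differently in the AKI libraries was not decided. Replication-dependent histone genes, which lack the tail, had medians of 0.32 and 0.49, between the bounds of 0.2 and 1 set for the test. The snoRNAs, which mostly lack it too, had medians of 2.02 and 2.0 (9 and 7 of 11 rose). Mitochondrial transfer RNAs were at 1.41 and 0.63 (8 and 3 of 13 rose). These classes were not part of the test and were set beside it after their values were seen. The snoRNA values go with a difference in recovery but do not decide it. Whether such a difference would bear on the mitochondrially encoded genes was not tested. An effect of the cells may also account for the higher respiratory chain and ribosomal protein genes, and was not tested apart from the batch.

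Podocyte, endothelial and matrix genes were lower in both MSC groups than in AKI kidneys. The trend over listed gene length is argued against here too, with the same limits, as the highest percentile of their 6 medians among matched random lists was 0. A second podocyte list, 12 genes of which 0 belong to another list and 11 reached 1 CPM in every group, had medians of -1.51 and -1.14 (10 and 9 genes fell), so a smaller share of podocytes in the tissue taken for RNA is a candidate explanation for the podocyte part; the most abundant, Npnt, Col4a4 and Col4a3 (317, 273 and 222 CPM in AKI), were at -0.54, -0.56 and -0.79 in UC and -0.46, -0.42 and -0.70 in pFUS_UC, and Rhpn1 at 0.45 and 0.23 (not called), so the falls were uneven. The lists do not separate fewer podocytes from less transcription in each, or a different part of the kidney from an effect of the cells. The batch that coincides with the AKI group stays open for these genes as well.

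The p53, injury and inflammatory lists were lower and the adipose list higher in pFUS_UC than in UC, with 0 single genes called by edgeR (1342 at an unadjusted p under 0.05, where chance gives 847, but 729 without UC replicate 1, 785 without pFUS_UC replicate 4 and 2209 without UC replicate 4; 44 by DESeq2, 0 by limma on log2(FPKM + 1)). A single library is argued against as the whole source of the 3 lower lists: with any 1 of the 8 libraries left out, the highest camera adjusted p, with the preset correlation, was 0.00807, though the inflammatory median of -0.60 was -0.28 without UC replicate 1 and -0.35 without pFUS_UC replicate 4, and the injury median of -0.48 was -0.31 without the latter. For the adipose list, whose median against AKI was -1.65 in UC and 0.27 in pFUS_UC, a difference in fat carried along with the kidney cannot be told apart from a change in the tissue, as a second adipocyte list (11 genes, 0 in another list, 8 at 1 CPM or more in every group; Scd1 at 578 and Lpl at 628 CPM in pFUS_UC) had a median of 0.33, between the bounds of 0.3 and 1. Members of this second list moved unevenly. Thrsp, Adrb3, Adig and Mrap (9.25, 2.25, 1.36 and 0.762 CPM in pFUS_UC) were at 1.47, 2.45, 1.67 and 1.57. The more abundant Scd1, Lpl, Cdo1, Cd36 and Aqp7 were at 0.07, 0.12, 0.18, 0.07 and -0.12, and Sncg and Lgals12 at 0.33 and 0.36. Whether the abundant members come from kidney cells was not tested. Ultrasound may account for the lower lists, but these calls were absent with an estimated correlation and with fry.

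Every one of the 35 ways to divide the 8 kidneys of a comparison 4 and 4 was fitted. For UC against AKI, 1 of 35 gave 8210 or more genes, the real one, and the highest other count was 5; for pFUS_UC against AKI, 1 of 35 gave 7463 or more, with a highest other count of 0. For both counts 1 of 35 is the lowest share this test can give, so chance division is argued against but not excluded. The other divisions mixed AKI and MSC kidneys within groups, which widens the fitted spread, so low counts in them were likely once the groups differ. The test does not separate group from batch. For pFUS_UC against UC the real count is 0, so all 35 divisions reach it whatever the data, and this says nothing about chance; the highest other count was 3.

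In 23 of 340 groups of 4 values, 1 library stood far from the other 3, where chance gives about 1 in 20. AKI replicate 1 stood apart for Havcr1 (20.2 CPM, others 84.8 to 98.1), Doc2g (1.78, others 0.628 to 0.779), Mir99ahg (3.61, others 1.38 to 1.61) and Snhg14 (4.86, others 0.544 to 0.937). AKI replicate 3 was lowest in the ribosomal protein share (1.64%, others 1.87 to 1.90%), Rps24 (144 CPM, others 194 to 204) and Rpl23 (121, others 147 to 152). UC replicate 1 was highest in Hbb-bt (1.06 CPM, others 0 to 0.123), and UC replicate 2 lowest in Plin1 (0.184, others 0.810 to 0.925). UC replicate 3 stood apart for Hspa1a (65.6 CPM, others 2.89 to 8.32) and Atp5c1 (389, others 503 to 524). UC replicate 4 was highest in Slc3a1 (174 CPM, others 119 to 127), Pdha1 (163, others 114 to 121), Sox18 (11.1, others 6.23 to 6.96) and Ccl21a (2.89, others 0.623 to 0.798). In pFUS_UC, replicate 1 stood apart for Lum (1.77 CPM, others 2.37 to 2.44), Bmp6 (60.7, others 37.2 to 39.6) and Ighm (4.24, others 7.0 to 7.53), replicate 2 for Nrf1 (17.9, others 19.1 to 19.3) and replicate 3 for Gapdh (577, others 14.2 to 26.3). Replicate 4 was highest on principal component 2 (30.3, others 1.45 to 5.42), in Col4a1 (200 CPM, others 157 to 164) and in Hbb-bt (30.9, others 0.0551 to 0.519).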

How the results depend on the processing

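Length and GC offsets and the fits without UC replicates 1 and 2 were chosen only after the results were seen. Counts of called genes stayed within 1.5 times 8210 and 7463 under DESeq2, RLE size factors, the filters, fits of only the groups compared, the replicate block (7791 and 7044), thinned counts, removal of abundant genes, limma, length and GC offsets (7591 and 6599) and each left-out library (7062 to 8357 and 5940 to 7694). A 2-fold minimum gave 3349 and 2840, as its construction requires, and without UC replicates 1 and 2 UC against AKI had 5416, with fewer samples. In pFUS_UC against UC, DESeq2 called 44 genes, no filter 13, the replicate block 2 (Plin1 and Cfd, Cfd being named after its values were seen), and each left-out library 0 to 1 (Prlr, without pFUS_UC replicate 4), against 0; among unchanged simulated genes DESeq2 called 33 and edgeR 2, and beyond this the cause was not tested. The relation of both comparisons with AKI fell to a Pearson coefficient of 0.76 with divided controls, which removes the sharing and also leaves 2 controls per comparison. Which of these lowered it was not tested, and the covariance went from 0.697 to 0.662.

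List calls fell from 14, 17 and 19 to 0, 0 and 0 with an estimated correlation, and in pFUS_UC against UC to 0 with fry, which asks another question; fry gave 16 and 16 in the others. It ended 2 of the 14 camera calls in UC against AKI, immediate early genes (adjusted p = 0.105) and macrophages (0.0568), and 4 of the 17 in pFUS_UC against AKI, p53 targets (0.248), NF-kappaB targets (0.0915), fatty acid oxidation (0.0677) and proximal tubule (0.0609). With an estimated correlation the medians 0.82 and 0.81 (complex I), 0.67 and 0.69 (complexes II to V) and 2.16 and 1.95 (mitochondrially encoded) stood with adjusted p values of 0.681 and 0.528, 0.681 and 0.528, and 0.75 and 0.661. Left-out libraries kept 158 of 168, 185 of 204 and 213 of 228 list calls, and length and GC offsets 13 of 14, 13 of 17 and 19 of 19. Of 111 calls of named genes per setting, length and GC offsets ended 4, limma 1, the replicate block 1, removal of UC replicates 1 and 2 ended 1, and left-out libraries 5 of 1332. The left-out fits of lists and genes include those without a library of the group not compared. Such fits bear on a call only through the shared spread and scaling.

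For the changes named from here on, the cause was not tested. Without UC replicates 1 and 2, pFUS_UC against UC medians became 0.19 (complex I), 0.16 (complexes II to V), 0.51 (mitochondrially encoded), 0.08 (biogenesis), 0.02 (fatty acid oxidation), -0.02 (endothelial) and -0.05 (heat shock), mt-Co3 0.25, mt-Nd1 0.35 and mt-Nd5 0.49; the heat shock median of pFUS_UC against AKI was -0.07, and Hspa1b in UC against AKI 0.56. The replicate block gave an injury median of -0.01 (pFUS_UC against AKI; -0.22 to 0.16 over left-out libraries), a heat shock median of 0.02 and Hspa1b 0.16 (pFUS_UC against UC), and Hspa1a -0.42 (UC against AKI). Limma on log2(FPKM + 1) gave Hspa1a -0.53 and Hspa1b 0.16, and with 0.1 in place of 1 it gave -0.81 and 0.18. Length and GC offsets gave Hspa1b 0.00 against AKI and 0.01 against UC, and a biogenesis median of 0.05 in pFUS_UC against AKI. Over left-out libraries heat shock medians ran from -0.02 to 0.14 (UC against AKI), -0.07 to 0.03 (pFUS_UC against AKI) and -0.04 to 0.08 (pFUS_UC against UC). In the last comparison complex I ran from -0.05 to 0.15, complexes II to V from 0.03 to 0.14, mitochondrially encoded from -0.39 to 0.05, biogenesis from 0.04 to 0.13, Hspa1a from -1.48 to 1.0, Hspa1b from -0.38 to 0.74 and Hbb-bt from -0.32 to 7.11. In UC against AKI, Cdkn1a ran from -0.52 to 0.09, Hspa1a from -1.67 to 0.67 and Hspa1b from -0.85 to 0.18; in pFUS_UC against AKI, Lcn2 ran from -0.54 to 0.37 and Hspa1b from -0.45 to 0.10.

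Simulated data of the same depth and replication had 67 genes changed at each of these sizes among 16947. In them edgeR called 10.4, 13.4 and 13.4% of 1.5-fold changes and 47.8, 55.2 and 53.7% of 2-fold changes. Changes of these sizes can thus be missed where few genes change. With 8210 and 7463 called genes, the adjustment is less strict in the comparisons with AKI, and these rates do not carry over to them.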

Other observations

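Long noncoding RNAs, snoRNAs and mitochondrial ribosomal RNAs were more often called higher than lower in both MSC groups against AKI. These classes were not tested as groups. Of 1591 long noncoding RNAs 694 rose and 39 fell in UC (median log2 fold change 0.89), and 637 rose and 40 fell in pFUS_UC (0.84). Of 11 snoRNAs, which guide modification of other RNAs, 9 and 7 rose (2.02 and 2.0), and both mitochondrial ribosomal RNAs rose in each (2.17 and 1.53). Of 13 mitochondrial transfer RNAs 8 rose in UC (1.41) and 3 in pFUS_UC (0.63), where 4085 and 3715 of all 16947 genes rose. Of 14172 protein-coding genes 2974 rose and 3954 fell in UC, and 2694 and 3600 in pFUS_UC.

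Log2 fold changes followed gene length in the comparisons with AKI. In the shortest of 10 equal parts of the protein-coding genes (median length 1339 bp) the median was 0.47 in UC and 0.47 in pFUS_UC, and in the longest (12385 bp) -0.31 and -0.27. Across genes the rank correlation with length was -0.26 and -0.27, and 0.05 for pFUS_UC against UC.

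Other lists with no camera call in any comparison included markers of neighbouring tissues and sex-biased kidney genes. Adrenal markers had medians of 0.41, 0.45 and -0.04 in UC against AKI, pFUS_UC against AKI and pFUS_UC against UC, skeletal muscle 0.49, 1.0 and 0.41, and pancreas and liver 0.06, 0.25 and 0.02. Male-biased genes had medians of -0.01, 0.23 and 0.55, and female-biased genes -0.09, 0.60 and 0.25. Proliferation genes had medians of 0.27, 0.12 and -0.07, DNA repair genes 0.13, -0.05 and -0.06, and interferon response genes -0.44, -0.30 and 0.13.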
